A study of Mus musculus with 5 samples.

How the data were processed

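RNA was sequenced from splenic germinal center B cells of 12-week-old mice, sorted by flow cytometry 7 days after immunization with sheep red blood cells. Per the labels' protocols, total RNA of the sorted cells, with an RNA integrity number above 8, was amplified with the Ovation RNA-Seq System V2 and sequenced on a HiSeq2500 as paired reads of 50 bases, with 35 to 40 M reads planned per library. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Cufflinks 2.0.2 and the genome build mm9. The counting tool, the gene annotation, the use of strand and the origin of the scaling factors are not given in the sources used here.

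The authors deposited 1 table of 38924 genes with a normalized signal for each of the 5 libraries. The values are read counts divided by a scaling factor per library: in each library 100% of the values above 0 were whole multiples of the smallest value, within 0.01 of a whole number. Dividing by that step gave back whole reads, which set the depth of each library and fed the count-based alternatives. No further scaling was applied to the deposited values in the main test. Gene names were in capitals. They were matched to GENCODE M21 and RefSeq GRCm38.p6, another build than the authors used, for spelling, gene type, length, GC content and gene order. Of the names, 37669 matched and 1255 did not, and 231 genes carried a repeated name. No coordinates are given for this reason.

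Libraries were grouped by the genotype in their labels into WT (Cγ1-Cre, 3 libraries) and DKO (both Relb and Nfkb2 floxed, with Cγ1-Cre, 2 libraries). The plan named limma for a table of FPKM values and edgeR, with its own filter, for a table of counts. The table held scaled counts, so limma was kept and the minimum mean value for testing was set at 10. This was done after the unit was known and before any test was run. The planned minimum of 1 was run as an added alternative. EdgeR was later run on the recovered reads, with the minimum of 10 in place of its own filter. Genes were tested with limma 3.58.1 in R 4.3.3, as a moderated two-sided test with a mean-variance trend on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of weakly expressed genes. Residual degrees of freedom were 3, and the prior added 5.92. Fixed gene lists, 35 in number with 816 members, were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry.

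Choices made before the data were examined were the groups, the test, the lists, most alternatives and the rule for naming genes. That rule took Relb and Nfkb2, then 12 genes per direction with the smallest p among genes whose groups did not overlap (to be filled in this way where too few passed the adjusted threshold), and up to 4 tested members of each list. Genes without a proper name were passed over. Bcl6, Cd3e and Ccr7, and all genes first named in the closing section, fall outside the rule and were chosen after their values were seen. A few further genes are not reported here, and counts of named genes leave them out. Alternatives were the pseudocount, the minimum value, quantile and TMM scaling, the replicate number as a block, and robust and weighted fits. Each library was also left out, and an estimated correlation was used for the lists. Fits without a DKO replicate hold 1 DKO library, so the spread within DKO is not seen there. Camera kept the preset correlation in them, and genes of most real lists varied more closely together than that. Their calls show how a list moves with single libraries and do not measure a difference by genotype. Replicate 3 exists only in WT, so the block leaves that library out of the comparison. It also leaves 1 residual degree of freedom in place of 3. Added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, minimum values of 1 and 50, the sex of the mouse or the level of T cell markers as a covariate, a correction for transcript length and GC content with splines of 5 degrees of freedom, the removal of WT replicate 2 together with DKO replicate 1 and, for antisense genes only, the share of mitochondrial ribosomal RNA as a covariate.

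The scripts were tested on simulated data with the libraries' own means and spread, with 200 genes changed in each of 10 runs. The gene test recovered 11.6% of genes changed 2-fold, 61.0% of those changed 4-fold and 74.7% of those changed 8-fold, and called 82 of 130420 unchanged genes. The true calls numbered 73, 414 and 517, so the share of false calls was above the threshold of 0.05. Camera found a list of 30 genes shifted by 0.50 (log2) in 10 of 10 runs and an unshifted list in 1 of 10, at an unadjusted p under 0.05. The simulated genes varied independently. In the real lists that camera called, the estimated correlation between genes ran from 0.20 to 0.56, so the runs do not give its error rate there. The median standard error of a log2 fold change was 0.33, so that a 95% interval spanned a fold of 1.67 on either side for a typical gene. Intervals from read numbers cover counting error only, since amplified reads are not independent molecules. The labels describe littermate mice but do not say that each library came from a separate animal, and p-values measure the spread between these libraries.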

Results

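The alternative NF-κB pathway acts through heterodimers of RELB with the p52 product of Nfkb2. Germinal center B cells of mice with both genes floxed and Cγ1-Cre (DKO, n = 2) were compared with those of Cγ1-Cre littermates (WT, n = 3) to ask which transcripts depend on this pair of factors. Cγ1-Cre recombines floxed alleles in B cells that transcribe the IgG1 constant region, which begins around germinal center entry. Library totals were 44885007, 33953377 and 57582464 reads in WT replicates 1 to 3 and 35154064 and 48178578 reads in DKO replicates 1 and 2. Mitochondrial ribosomal RNA took 62.4%, 51.6%, 70.9%, 47.0% and 60.6% of these totals, in the same order. Genes outside the mitochondrial genome kept 15.4, 15.5, 15.5, 17.7 and 17.6 M reads, again in this order. Between 17843 and 18744 genes had at least 1 read in a library.

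Both targeted genes had low transcript levels in the DKO libraries, with a clear gap between those libraries. Relb was at 136, 171 and 117 normalized counts in WT and at 56.9 and 10.7 in DKO, so that DKO replicate 1 kept 40.2% and DKO replicate 2 kept 7.59% of the WT mean. Nfkb2 was at 657, 601 and 445 in WT against 298 and 73.5 in DKO, or 52.5% and 13.0% of the WT mean. The log2 fold changes were −2.43 ± 0.63 (SE) for Relb and −1.91 ± 0.51 for Nfkb2. In limma's test both missed the threshold over all genes (adjusted p = 0.823) and both passed when adjusted over the list alone, that of the alternative NF-κB components (adjusted p = 0.0248). Counts cover the whole gene, and the deleted exons were not counted separately.

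Bcl6, the master repressor of the germinal center program, had similar mean levels in both genotypes, at 10928 ± 1100.0 (SD) normalized counts in WT and 10075 ± 266 in DKO. Gaps larger than the spread within the groups appeared in other genes. Rgs13, a germinal center regulator of G protein signaling, averaged 5629 ± 2431 in WT and 1733 ± 363 in DKO, and the fatty acid receptor Cd36 averaged 861 ± 85.1 and 261 ± 61.3. The peptide transporter Slc15a2 was at 97.4, 357 and 231 in WT and at 1243 and 1282 in DKO.

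No gene among the 13242 tested passed the adjusted threshold in limma (smallest adjusted p = 0.148). At an unadjusted p under 0.05 there were 489 genes higher and 314 lower in DKO, 803 in all where chance alone gives 662. After the added correction for length and GC content the split was 342 higher and 403 lower. EdgeR on the recovered reads also called 0 genes, with 445 higher and 303 lower at an unadjusted p under 0.05. DESeq2 called 16 higher and 13 lower. In 3102 genes, 23.4% of those tested, the DKO and WT values did not overlap, where chance gives 20%.

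The 12 genes with the smallest p among those higher in DKO, none of them past the adjusted threshold, were Snap25, Slc15a2, Mtcp1, Zfp142, Phykpl, Clk4, Gcfc2, Rnf24, Ddx26b, Zkscan3, Fbxo33 and Kmt2a. Snap25, which encodes a SNARE protein of regulated exocytosis, was at 384 normalized counts in DKO replicate 1 and 77.6 in DKO replicate 2. It had 2 reads over the WT libraries and 532 over the DKO libraries, a ratio of 333 per unit of depth with a 95% interval of 91.7 to 2756 from counting alone. For Slc15a2 the log2 fold change was 2.65 ± 0.47 (adjusted p = 0.505, limma). Kmt2a, a histone H3K4 methyltransferase, was at 14359, 12887 and 10888 in WT and at 21451 and 23927 in DKO, and Clk4, a kinase of splicing factors, had a log2 fold change of 0.75 ± 0.19. Among these 12 genes, DESeq2 called Snap25, Slc15a2, Mtcp1, Zfp142, Phykpl, Clk4 and Kmt2a.

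Lower in DKO by the same rule, and likewise not passing, were Cd36, As3mt, Rgs13, Tox2, Neurl1a, Lck, Enpp4, Gstt3, Zfp51, Cdk14, Evc and Relb. Cd36 had the smallest p of these, with a log2 fold change of −1.73 ± 0.24 (adjusted p = 0.241, limma). Tox2, an HMG-box factor known from follicular helper T cells, was at 1035, 177 and 226 in WT and at 28.0 and 42.1 in DKO. Lck, a Src family kinase, averaged 877 ± 131 in WT and 444 ± 8.73 in DKO. As3mt and Neurl1a lie near Nfkb2 in the genome, with log2 fold changes of −1.40 ± 0.26 and −4.47 ± 0.94. DESeq2 called Cd36, As3mt, Rgs13, Tox2, Neurl1a, Lck and Enpp4.

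**Figure D1:**
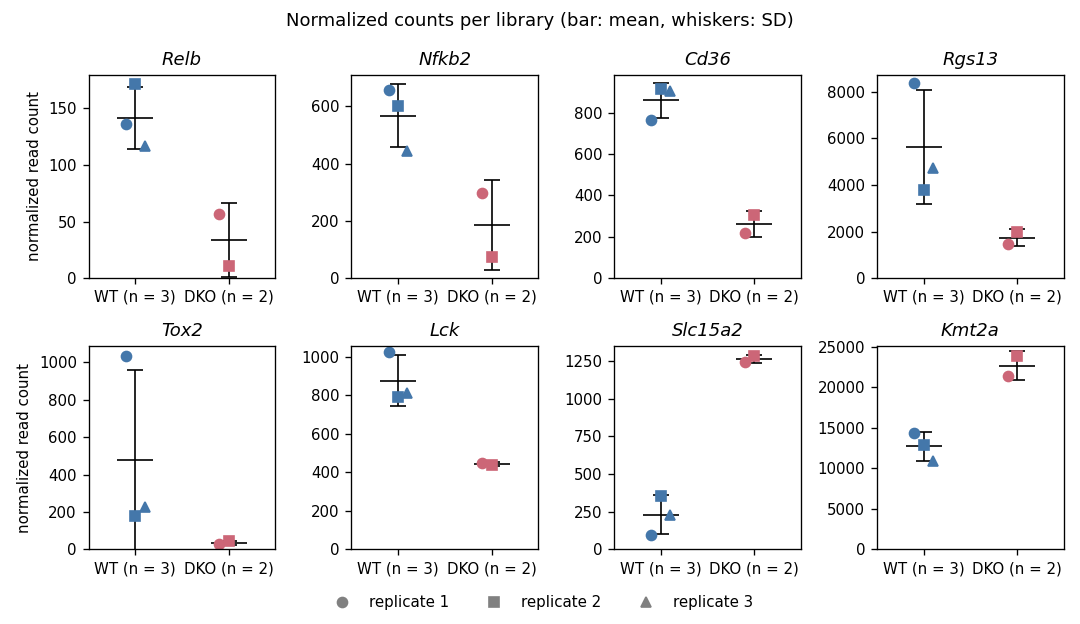
Normalized read counts of 8 genes in each library, on linear axes from 0, for WT (n = 3) and DKO (n = 2); points are libraries, the long bar is the mean and the whiskers are the SD. Relb and Nfkb2 are lowest in DKO replicate 2, at 10.7 and 73.5. In each of the 8 panels the DKO points lie on the same side of all WT points. The naming rule required this of Cd36, Rgs13, Tox2, Lck, Slc15a2 and Kmt2a.

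Other members of the NF-κB lists had fold changes in both directions, and none of them passed the test. Of 11 alternative NF-κB components, 4 had higher and 7 lower values in DKO, and only Relb and Nfkb2 passed when adjusted over the list alone. Cd40, the receptor that feeds this pathway, averaged 1035 ± 118 in WT and 702 ± 303 in DKO. Among 16 canonical components, the kinase gene Ikbkb and the atypical inhibitor Nfkbiz had higher means in DKO, 2907 ± 801 against 1690 ± 526 in WT and 569 ± 188 against 291 ± 121, while Bcl3 and Bcl10 had log2 fold changes of −0.69 ± 0.27 and −0.53 ± 0.23; none passed over the list alone. Bcl3 is also a genomic neighbour of Relb. NF-κB target genes were lower in 22 of 32, with a median log2 fold change of −0.20 and Traf1 at −0.53 ± 0.22. Camera called neither the components (adjusted p = 0.155 for the alternative and 0.708 for the canonical list) nor the targets (adjusted p = 0.0989). The alternative components and the targets were lowest in DKO replicate 2, which kept fewer Relb and Nfkb2 reads than DKO replicate 1. Their mean log2 levels deviated from the mean over libraries by −0.57 and −0.22 there, and by 0.07 and 0.05 in DKO replicate 1. The alternative list holds Relb and Nfkb2 themselves, and its mean log2 fold change was −0.42 against a median of −0.05. Its camera call with the replicate number as a block (adjusted p = 0.0186) therefore cannot be told from the loss of the targeted genes. The targets passed in camera without WT replicate 2 (0.0459) and with a lower or no minimum value (0.0353 at 1, 0.0477 at 5 and 0.0430 with none).

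Genes of germinal center identity were higher in 8 and lower in 17 of 25, and Rgs13 was the member that passed when adjusted over the list alone (adjusted p = 0.0189). Bach2, a repressor of plasma cell differentiation, went the other way, with 16566, 16775 and 11155 normalized counts in WT and 25304 and 24445 in DKO. Among 16 dark zone genes, Rgs13 (adjusted p = 0.0121) and Pdia4 (adjusted p = 0.0381), a disulfide isomerase of the endoplasmic reticulum, passed over the list alone, both lower in DKO. Of 23 light zone genes, 16 were lower, among them the activation-induced factors Egr1 (−0.56 ± 0.20) and Egr2 (−0.60 ± 0.26), with none passing over the list alone. Plasma cell genes were lower in 12 of 18, with Txndc5 at −0.59 ± 0.22 and Eaf2 at 0.66 ± 0.25. At the main setting none of these groups passed in camera, with an adjusted p of 0.175 for identity, 0.0897 for dark zone, 0.0989 for light zone and 0.0562 for plasma cell genes. These calls moved with single libraries: identity (0.0071) and dark zone genes (0.0024) passed as lower without WT replicate 2. Dark zone genes had a positive median of 0.17 without DKO replicate 1. Their mean log2 level deviated from the mean over libraries by −0.37 in DKO replicate 1 and 0.11 in DKO replicate 2. That of light zone genes deviated by 0.05 and −0.21. Plasma cell genes passed as lower without WT replicate 2 (0.0230) or WT replicate 3 (0.0344), with library weights (0.0325) and at a minimum value of 5 (0.0238). They also passed with the replicate block (0.0186), which likewise leaves WT replicate 3 out of the comparison. With no minimum value both plasma cell (0.0150) and dark zone genes (0.0468) passed as lower. With settings added after seeing the data, both passed at a minimum value of 1 (0.0118 and 0.0369), and plasma cell genes with the sex covariate (0.0310). Without both WT replicate 2 and DKO replicate 1, which leaves 1 DKO library, plasma cell and light zone genes were lower too.

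Among the fixed lists, those that passed as groups were shifted down by small amounts and covered growth, energy metabolism, protein folding, interferon response and antigen presentation. Camera with the preset correlation called 9 of the 35 lists, all lower in DKO. None held with an estimated correlation (adjusted p = 0.921 for each of the 9), and fry called none. The replicate number as a block leaves WT replicate 3 out of the comparison. With it, antigen presentation (adjusted p = 0.0112), interferon response (0.00027) and ribosomal protein genes (0.0426) still passed. The other 6 lists did not, from 0.243 for the unfolded protein response to 0.619 for nucleotide synthesis. In these 9 lists no member passed over all genes or when adjusted over the list alone, and the medians lay between −0.16 and −0.33.

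Cytosolic ribosomal protein genes were lower in 36 of 42 (median −0.22, adjusted p = 0.00031, and 0.921 with an estimated correlation). Rplp0 was the member with the smallest p, at 3658 ± 439 in WT and 2050 ± 1447 in DKO. Genes of Myc targets and ribosome biogenesis were lower in 29 of 34 (adjusted p = 0.0112, and 0.921 with an estimated correlation), including the nucleolar chaperone Nolc1, at 1345, 1324 and 1559 in WT and 716 and 1327 in DKO. Oxidative phosphorylation genes were lower in 37 of 46 (median −0.16, adjusted p = 0.0039, and 0.921 with an estimated correlation), with Ndufs6 of complex I at 418 ± 34.2 against 236 ± 76.2 and Sdhd of complex II at 760 ± 103 against 464 ± 71.0. Genes of the tricarboxylic acid cycle were lower in 19 of 23 (adjusted p = 0.0174), nucleotide synthesis genes in 23 of 28 (adjusted p = 0.0136) and replication-dependent histone genes in 23 of 28 (adjusted p = 0.0039), each with an adjusted p = 0.921 with an estimated correlation. Ribosomal protein and histone genes have near-identical copies, and reads shared with these leave single members uncertain. In DKO replicate 1, which also carried more T cell and naive B cell transcripts, these lists were lowest: without it the adjusted p was 0.125 for ribosomal proteins, 0.439 for ribosome biogenesis, 0.377 for oxidative phosphorylation, 0.853 for the tricarboxylic acid cycle, 0.336 for nucleotide synthesis and 0.701 for histones. Without WT replicate 3 ribosomal proteins passed (adjusted p = 0.0170) and the other 5 did not, from 0.220 for oxidative phosphorylation to 0.632 for nucleotide synthesis. With the T cell marker level as a covariate, added after seeing the data, ribosome biogenesis (adjusted p = 0.0844), the tricarboxylic acid cycle (0.0851) and nucleotide synthesis (0.0851) did not pass.

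Antigen presentation genes were lower in 16 of 19 (median −0.32, adjusted p = 0.0030, and 0.921 with an estimated correlation). B2m, the light chain of class I molecules, averaged 28296 ± 3584 in WT and 19305 ± 5750 in DKO, H2-D1 5421 ± 249 and 3823 ± 1288, and the lysosomal protease Ctss 4059 ± 474 and 2861 ± 217. Interferon response genes were lower in 19 of 25 (median −0.33, adjusted p = 0.0403, and 0.921 with an estimated correlation), led by Oasl2 at 183 ± 47.7 and 47.0 ± 49.2. Unfolded protein response genes were lower in 13 of 19 (median −0.22, adjusted p = 0.0112, and 0.921 with an estimated correlation), with Pdia4 at 1691 ± 202 against 998 ± 90.6 and Hyou1 at 2350 ± 272 against 1605 ± 49.1. The first 2 of these lists were lowest in DKO replicate 2, which also had the lowest Relb and Nfkb2 counts, and neither passed without it. In DKO replicate 1 the mean log2 level of antigen presentation genes was 12.27, within the 12.22 to 12.36 of WT. That of interferon genes was 6.83, within the 6.28 to 7.47 of WT. The interferon call also ended without WT replicate 2 (adjusted p = 0.665). That of the unfolded protein response ended without WT replicate 1 (0.0574), where its median stayed at −0.22, and without WT replicate 3 (0.153). It ended without DKO replicate 1 too. The level of this list in DKO replicate 2, 10.33, lay within the 10.21 to 10.56 of WT. Leaving out both WT replicate 2 and DKO replicate 1, a setting added after seeing the data, keeps DKO replicate 2 as the only DKO library. The mean log2 level of antigen presentation genes in DKO replicate 2 was 11.79, below the 12.22 to 12.36 of WT. That of interferon genes was 6.15, below the 6.28 to 7.47 of WT. That of histone genes was 9.09, within the 8.80 to 9.49 of WT.

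**Figure D2:**
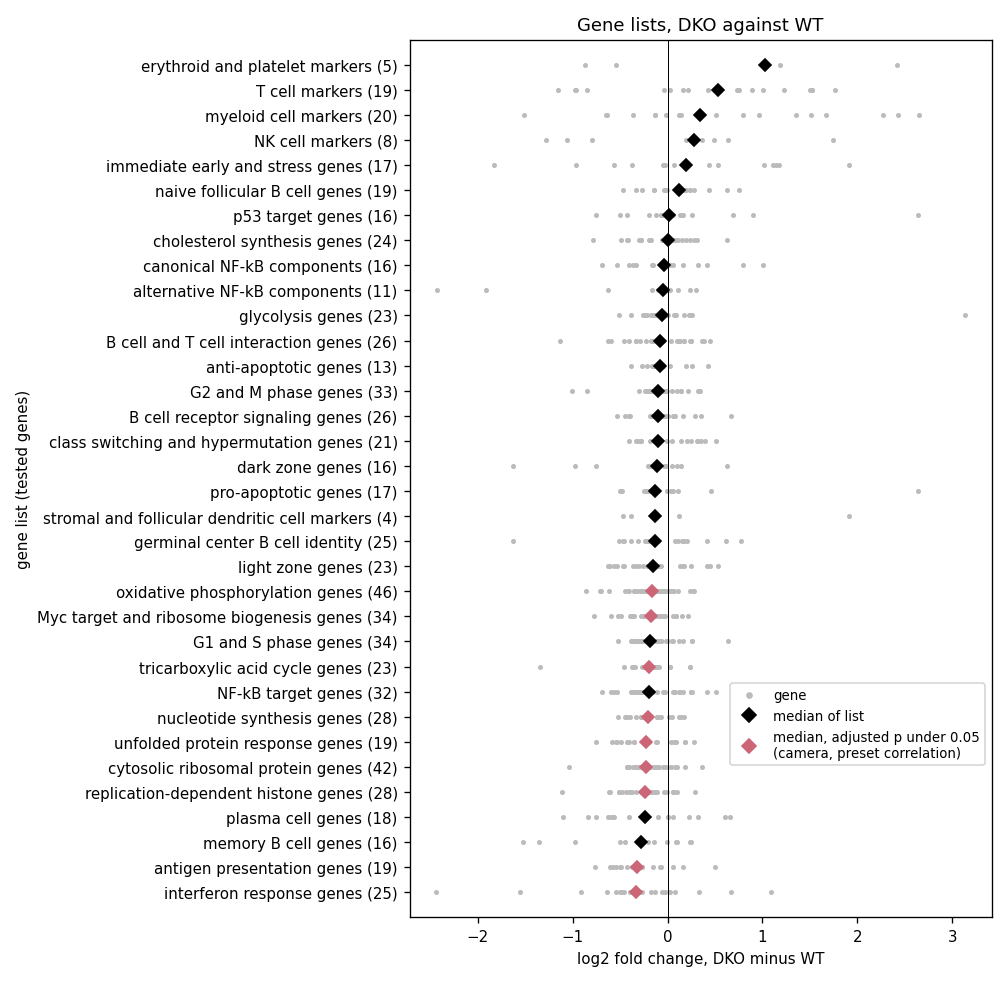
Log2 fold changes, DKO minus WT, of the tested members of 34 gene lists; grey points are genes and diamonds are list medians, red where camera with the preset correlation gave an adjusted p under 0.05. The 9 red medians lie between −0.16 and −0.33, and the other lists did not pass. Medians of the T cell, NK cell, myeloid, and erythroid and platelet lists lie right of 0. The stromal median lies left of it, at −0.13.

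Cell cycle genes did not pass as groups at the main setting, and their calls varied with the minimum value and the libraries used. G1 and S phase genes were lower in 26 of 34 (adjusted p = 0.0897) and G2 and M phase genes in 25 of 33 (adjusted p = 0.252, camera), and the kinetochore genes Cenpe and Cenpf had log2 fold changes of −0.85 ± 0.29 and −1.01 ± 0.40. G1 and S phase genes passed as lower with no minimum value (adjusted p = 0.0452) and with a minimum of 1, added after seeing the data (0.0353). The direction of both groups depended on the DKO library. Their mean log2 levels deviated from the mean over libraries by −0.33 (G1 and S) and −0.27 (G2 and M) in DKO replicate 1. In DKO replicate 2 they deviated by 0.18 and 0.16. Without DKO replicate 1, which leaves 1 DKO library, the median log2 fold changes were 0.12 and 0.15. Both groups passed in camera as lower without WT replicate 2 (adjusted p = 0.0020 and 0.00093). B cell receptor signaling genes were lower in 19 of 26 (adjusted p = 0.256), while the inhibitory receptor Fcgr2b within this list averaged 779 ± 41.4 in WT and 1244 ± 118 in DKO. Class switching and hypermutation genes were lower in 12 of 21 (adjusted p = 0.898), genes of contact with T cells in 14 of 26 (0.464) and memory B cell genes in 12 of 16 (0.155). Both of the last groups were lowest in DKO replicate 2, and without it both had positive medians (0.20 and 0.38). Memory B cell genes passed as lower without WT replicate 3 (0.0205) and with the replicate block (0.00063), which likewise leaves that library out of the comparison. With covariates added after seeing the data they passed for sex (0.0344) and for T cell markers (0.0168). B cell receptor genes passed without WT replicate 1 (0.0351). Glycolysis genes were lower in 13 of 23 (0.625) and cholesterol synthesis genes in 11 of 24 (0.625, and 0.0046, lower, without WT replicate 2). Anti-apoptotic genes were lower in 9 of 13 (0.695), pro-apoptotic genes in 11 of 17 (0.563) and p53 targets in 8 of 16 (0.696). Of 17 immediate early and stress genes 10 were higher (0.666), with Jun at 84.1 ± 24.8 in WT and 193 ± 104 in DKO and Fosb, a genomic neighbour of Relb, at 18.4 ± 12.7 and 70.1 ± 42.2. This list deviated from the mean over libraries by 0.59 in DKO replicate 2 and by −0.31 in DKO replicate 1.

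Transcripts of other cell types varied widely between libraries of the same genotype. WT replicate 2 and DKO replicate 1 had more T cell, NK cell and naive B cell transcripts than the other 3 libraries. Cd3e stood at 10.7, 363 and 7.69 in WT and at 163 and 26.4 in DKO, and the chemokine receptor Ccr7 at 178, 575 and 112 against 401 and 79.3. Between genotypes camera passed none of these lists at the main setting: T cell markers were higher in 14 of 19 (adjusted p = 0.696), NK cell markers in 5 of 8 (0.905), naive follicular B cell genes in 11 of 19 (0.695), myeloid markers in 13 of 20 (0.395), erythroid and platelet markers in 3 of 5 (0.696) and stromal markers in 2 of 4 (0.898). Without WT replicate 2, T cell markers (adjusted p = 0.0037, median 1.51) and naive B cell genes (0.0020) passed as higher. The mean log2 level of naive B cell genes deviated from the mean over libraries by 0.56 in DKO replicate 1 and −0.44 in DKO replicate 2. Myeloid markers passed as higher without WT replicate 1 (0.0039). Erythroid and platelet markers passed as higher with no minimum value (0.0192) and at a minimum of 1, added after seeing the data (0.0276). Lck passed when adjusted over the T cell list alone (adjusted p = 0.0340), lower in DKO, and its values did not follow those of Cd3e. For NK cells the median was positive (0.28) and the camera direction lower, and the stromal median was −0.13 with the camera direction higher. Y-linked genes were present in WT replicate 1 and DKO replicate 1 and near 0 in the other 3 libraries. Ddx3y was at 1762 and 1778 in those male libraries. The 5 sex-linked genes tested had an adjusted p of 0.666 in camera.

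**Figure D3:**
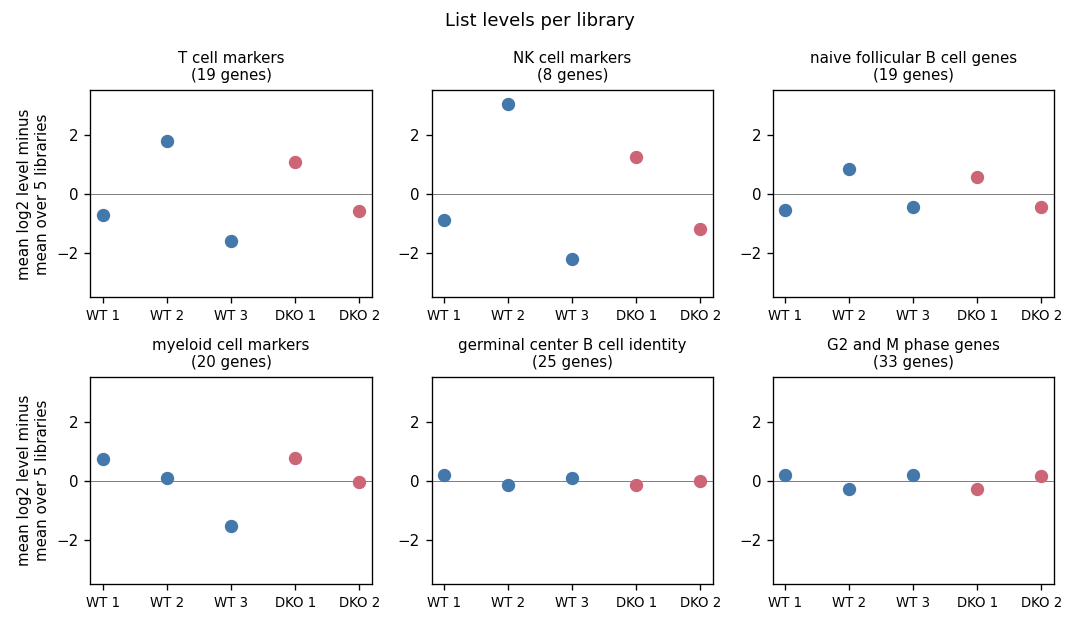
Mean log2(value + 1) of 6 gene lists in each library, as the deviation from the mean over the 5 libraries; blue points are WT and red points DKO. T cell, NK cell and naive B cell lists are above 0 in WT replicate 2 and DKO replicate 1 and below 0 in the other 3 libraries.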

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

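Tests chosen after the data were seen are those with a minimum value of 1 or 50, sex or T cell markers as a covariate, the length and GC correction, edgeR, DESeq2 and the removal of WT replicate 2 with DKO replicate 1. Across 22 alternatives the 65 named genes counted here gave 1424 fold changes, of which 0 changed sign. Of these fold changes 22 moved past the adjusted threshold, all under the replicate block or DESeq2. Most of the 65 genes were chosen for groups without overlap or an unadjusted p under 0.05 in these data. Most list members that the rule named with a larger p were not followed here, so the 0 does not cover them. Leaving out a library cannot turn the sign where the groups do not overlap, so few sign changes could arise. Outside the 65, Ighg1 went from 0.43 to −0.14 without WT replicate 1. Against 0 genes in either direction, library weights called 1 higher and 1 lower, the T cell marker covariate 2 and 1, the removal of both marker-rich libraries 1 and 1, and DESeq2 16 and 13. Leaving out each library gave 0 to 1 higher and 0 to 1 lower at the adjusted threshold, and 91 to 736 higher and 215 to 372 lower at an unadjusted p under 0.05. Other unadjusted counts outside 1.5 times those of 489 higher and 314 lower were 907 higher with no minimum value, 765 higher with a minimum of 1, 484 lower with the T cell covariate, and 197 higher and 208 lower without both marker-rich libraries. With the replicate number as a block, 14 genes were higher and 22 lower at the adjusted threshold, 270 were higher at an unadjusted p under 0.05, and 6 lists were lower, of which 3 were among the 9 of the main test. It ended the calls of ribosome biogenesis (adjusted p = 0.421), oxidative phosphorylation (0.365), the tricarboxylic acid cycle (0.566), nucleotide synthesis (0.619), histones (0.566) and the unfolded protein response (0.243), and added those of alternative NF-κB components, plasma cell and memory B cell genes. The block has no known design behind it. It leaves 1 residual degree of freedom, so its calls rest on replicates 1 and 2 of each genotype. The 2 DKO deviations from their mean mirror each other, so correlations with WT (0.005 for replicate 1, −0.28 for replicate 2) cannot test pairing. For lists, against 9 lower and 0 higher, an estimated correlation gave 0 lower. A minimum of 1, no minimum, and the removal of both marker-rich libraries each gave 1 higher. That removal left 1 DKO library. It also added lower calls for alternative NF-κB components, NF-κB targets, memory B cell genes and genes of contact with T cells. The first of these lists holds Relb and Nfkb2. The higher call of that removal was that of immediate early genes. Leaving out each library gave 5 to 15 lower and 0 to 2 higher. The call of the tricarboxylic acid cycle also ended with quantile scaling (adjusted p = 0.0557), a minimum of 50 (0.0605) and the sex covariate (0.0552), that of nucleotide synthesis with the sex covariate (0.0661), and that of interferon response with library weights (0.0590) and the length and GC correction (0.0633). Without DKO replicate 1 the medians of ribosome biogenesis and nucleotide synthesis genes changed sign, to 0.059 and 0.078; with each library left out they ranged from −0.38 to 0.059 and from −0.45 to 0.078. Apart from fewer samples or other gene numbers, the cause was not tested. The planned edgeR test had depended on a table of counts, and was run on recovered reads instead. There are 10 ways to divide the 5 libraries into 3 and 2. With the real division included, 4 gave at least its 803 genes at an unadjusted p under 0.05 (highest other 1650). Again with the real division included, 7 gave at least its 9 lists (highest other 24). These are too few divisions for a share under 0.05. The division with 1650 genes sets WT replicate 2 and DKO replicate 1 against the rest and points to a structure of the libraries.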

Other observations

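Tests in this part chosen only after the result was seen are those of immunoglobulin constant regions and gene types, of genomic DNA, of mitochondrial RNA, of other cells as a source of noncoding or marker transcripts, of sex, of the germinal center restricted genes and of the genes near Nfkb2 and Relb.

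Among immunoglobulin heavy chain transcripts, those of several switched classes had lower means in DKO without passing the test. Ighg2c was at 11580, 922 and 1207 normalized counts in WT and at 442 and 221 in DKO, Ighg2b averaged 3423 ± 2542 (SD) and 1129 ± 473, and Ighg3 7836 ± 3239 and 3541 ± 1510. In limma these 3 missed the threshold when adjusted over the 9 constant region genes (adjusted p = 0.0584), as did Igha (0.0935). The log2 fold change was −0.06 ± 0.30 for Ighm and 0.43 ± 0.52 for Ighg1, the class whose locus carries the Cre. Ighe had a higher mean in DKO, 333 ± 96.1 against 229 ± 122 in WT, with a log2 fold change of 0.64 ± 0.42 (0.264 adjusted over these genes). WT replicate 1 set much of the size: without it the log2 fold change was −1.75 for Ighg2c instead of −2.90, −0.86 for Ighg2b instead of −1.42, −0.83 for Ighg3 instead of −1.13, −0.14 for Ighg1 and 1.04 for Ighe. Near-identical sequence between the IgG genes leaves single members uncertain.

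Noncoding RNA genes had higher medians in DKO as classes. The median log2 fold change was 0.73 for 345 antisense genes, 0.51 for 243 lincRNA genes and 0.83 for 75 snoRNA genes, against −0.03 for 10646 protein-coding genes, and in each noncoding class both DKO libraries lay above all WT libraries. Among antisense genes 54 were higher and 0 lower at an unadjusted p under 0.05 in limma, and 3 passed when adjusted over the class. Protein-coding genes numbered 259 higher and 271 lower at this level. Neat1, a scaffold of nuclear paraspeckles, averaged 483 ± 177 in WT and 1186 ± 472 in DKO. Camera gave antisense genes an adjusted p of 4.17e-13. With an estimated correlation none of these 3 classes passed, with an adjusted p of 0.187 for antisense, 0.187 for lincRNA and 0.120 for snoRNA genes. Protein-coding genes, with their median of −0.03, passed in that test (adjusted p = 0.0099), though the levels of this class overlapped between DKO and WT libraries. The share of mitochondrial ribosomal RNA was highest in WT replicate 3 (70.9%), the library with the lowest antisense level, and lowest in DKO replicate 1 (47.0%), the library with the highest. The antisense median was 0.51 with that share as a covariate and 0.55 without WT replicate 3.

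Candidate explanations for the noncoding pattern were weighed against these values. Genomic DNA is argued against by its size: olfactory receptor reads ranged from 12.0 to 39.3 per M reads in WT and were 37.7 and 16.1 in DKO, and DNA at that density would give at most 0.431% of the reads of antisense genes in any library. A trend with transcript length and GC content is not the whole cause, since its removal left an antisense median of 0.58, although that of snoRNA genes dropped to 0.22. Other cells that T cell markers track are not the whole cause, as the antisense median was 0.67 with that marker level as a covariate and 0.81 without WT replicate 2 and DKO replicate 1, but within each genotype the marker-rich library was the highest, and such cells may add to the spread. A larger share of nuclear or unspliced RNA, by genotype or by sample handling, may contribute and was not tested, and with no strand information reads from introns of host genes cannot be separated from antisense transcripts.

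WT replicate 2 and DKO replicate 1 were high in markers of other cells, and DKO replicate 1 also kept more Relb and Nfkb2 reads than DKO replicate 2. On average over these 2 libraries against the other 3, the lists were higher by 2.38 (log2) for T cells, 3.56 for NK cells and 1.17 for naive B cells, which is consistent with more lymphocytes of other types despite the gate, but the myeloid list, 0.71 higher on average, was at 6.46 in WT replicate 1 and 5.83 in WT replicate 2, which argues against an even share of all spleen cells. Sex is argued against, as WT replicate 2 was 1.27 above the other female libraries on the naive B cell list, and so is a length and GC trend, whose removal left a difference of 1.103. Whether such cells, with intact alleles, could also account for the residual Relb and Nfkb2 reads stays open: germinal center restricted genes in DKO replicate 1 were at a median of 0.849 times their level in DKO replicate 2, while Relb differed 5.30-fold and Nfkb2 4.05-fold. Incomplete recombination within germinal center B cells was not tested.

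Genes near Nfkb2 differed more often than genes elsewhere. Among the 20 tested neighbours on each side, 9 of 40 near Nfkb2 (As3mt, Neurl1a, Hps6, Psd and Actr1a lower, Sfxn3, Btrc, Taf5 and Gm19557 higher) and 4 of 40 near Relb (Fbxo46, Gemin7 and Bcl3 lower, Fosb higher) had an unadjusted p under 0.05, against 2.15 expected, and a share of 0.0027 of 10000 random pairs of windows held as many. The test was prompted by As3mt, and without 3 neighbours already seen among the top genes 10 were left and the share was 0.0212; the count for Nfkb2 alone was reached by 0.204% of windows, or 1.46% without the seen neighbours, and that for Relb by 17.0%. Leaving out single libraries lowered the total from 13 to between 6 and 9, and other divisions of the libraries gave 0 to 8. Strain sequence carried along with the targeted loci is consistent with this, but an effect of the modified Nfkb2 allele on its surroundings may give the same values.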
